A study of Mus musculus with 36 samples.

How the data were processed

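Liver RNA was measured in 36 samples of C57BL6/J mice, the standard inbred laboratory strain, kept at 22 °C or 30 °C and injected with lipopolysaccharide (LPS), a cell-wall component of Gram-negative bacteria that sets off systemic inflammation. Samples were taken at 0, 4, 12 and 24 h. Libraries followed a modified CEL-Seq2 protocol, per the labels' protocols. In this method reverse transcription starts at the poly(A) tail with a primer that carries a sample barcode and a unique molecular identifier (UMI), and the cDNA is amplified linearly, so that reads come from the 3' ends of transcripts. Here it was applied to bulk RNA rather than single cells. The sex of the mice, the LPS dose, the tool versions, the transcript index, the genome build and whether UMIs were collapsed are not given in the sources used here.

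Reads were trimmed with Trimmomatic, quantified with kallisto and summarised with sleuth, per the submitters' processing notes. For each gene and sample, 2 values were deposited, and both were used here as signal. The main value is the deposited signal named scaled reads per base in the authors' table. The second is named TPM, but its sum per library ran from 757040 to 1746038 rather than being a fixed total, so it is not plain TPM. How the authors scaled either value between libraries is not given in the sources used here. The design fixed before the data were examined had assumed estimated counts summed per transcript. The signal is not a count, so it was tested on a log scale, and the count models planned for raw counts were not used.

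The table holds 34829 Ensembl genes, of which 34406 identifiers matched a symbol in the reference annotation (GENCODE mouse release 21, GRCm38) and 423 did not. A value above 0 in at least 1 library was found for 22490 genes. Every value column could be tied to a sample. In each library the commonest low values were whole multiples of 1 step, taken as the worth of 1 read. Dividing the sum of values by this step gave 557000 to 2744000 estimated reads per library (median 1009000). Between 16.8% and 19.6% of the values in a library were whole multiples of the step within 0.01 read (55.2% to 63.2% for genes with 1 transcript), so whole reads could not be recovered for most genes. A value of 3 reads corresponded to 1.33 to 5.05 units of signal, depending on the library. Values near or below that level carry little information, and these limits cover counting error only. A log2 difference of a gene whose lower group lies there depends on the 1 added before the log and is not a bound. No log2 difference is given where every library of a group was listed at 0. PCR or UMI duplicates could not be separated in these values.

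Groups were taken from the labels: 4 samples at 22 °C and 5 at 30 °C for 0 h, 4 and 4 for 4 h, 5 and 4 for 12 h, and 5 and 5 for 24 h. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples. The 8702 genes with a mean signal of at least 5 over all samples were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(signal + 1), two-sided, with 1 mean per group and all 36 samples in 1 fit, so that the 13 contrasts share an estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Log2 differences are on the log2(signal + 1) scale, which understates the change of low genes, and are given ± SE. Group values are mean ± SD of the signal. The contrasts were 30 °C minus 22 °C at each time, each later time minus 0 h at each temperature, and the interaction, which is the change since 0 h at 30 °C minus that at 22 °C.

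A set of 46 gene lists was fixed before the data were examined. The 42 with at least 3 tested members were tested with limma's camera, a test of whether the members moved more in 1 direction than the other genes, with its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists in each contrast. Lists share members. Each call was tested again with the correlation estimated from the data. For each list the members that passed were counted after adjustment over all genes and after adjustment over the list alone. Of 235 list calls over the 13 contrasts, 72 held with the estimated correlation.

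The rule for named genes was also fixed beforehand: the 5 largest rises and falls with an official symbol and a mean of at least 20 in the higher group, up to 4 members of smallest p from lists that passed or had at least 3 changed members, and 15 genes followed in every contrast. Some genes that the rule names are not reported here. Genes with near-identical copies are uncertain because kallisto divides shared reads among them: Saa1 and Saa2, Hspa1b, the Mup, Cyp2c, Cyp3a, Gbp and H2-Q families. For 102 genes with a mean of at least 5, the values were identical to those of another gene in every library. Chromosome positions come from the annotation and are 1-based.

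Alternatives chosen before the data were examined were pseudocounts of 0.5 and 5, no filter, a mean of at least 20, trimmed-mean (TMM) and upper-quartile rescaling, the TPM values, a fit on the groups of a contrast alone, array weights, a replicate block, and leaving out each library. Leaving 30 °C 4 h replicate 4 out of every contrast and limma's voom precision weights were added after the data were seen. The limma and camera steps were tested on simulated data with known changes in 100 genes of each size among 8702. Of genes changed by 1 and by 2 log2 units, 30% and 72% were recovered for the 24 h temperature contrast, and 14% and 50% for the 24 h interaction. The simulated genes varied independently and few of them were changed. These shares therefore do not give the recovery in the real contrasts. Tables were read with version 1.17.8 of data.table, Python 3.11.15 and pandas 2.3.3, and figures were drawn with Matplotlib 3.10.9.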

Results

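The liver response to LPS was followed over 24 h at 22 °C, ordinary room temperature, and at 30 °C, a warm temperature at which mice spend little energy on keeping warm. The comparisons ask which liver genes change after LPS at each temperature and where the temperatures differ. The labels name no group kept without LPS at the later times. A change since 0 h may therefore also come from the time of day, the injection or feeding, which cannot be told apart from LPS here. The 36 libraries held 557000 to 2744000 estimated reads each. Mean depth at 0 h was 835000 ± 112000 reads at 22 °C (SD, n = 4) and 731000 ± 103000 at 30 °C (n = 5). At 4 h it was 1311000 ± 136000 (n = 4) and 1870000 ± 966000 (n = 4). At 12 h it was 1165000 ± 279000 (n = 5) and 1012000 ± 72000 (n = 4). At 24 h it was 856000 ± 58000 (n = 5) and 1425000 ± 600000 (n = 5). The correlation of log2 values between libraries of a group ran from 0.775 to 0.932. No library was therefore an exact copy of another in its group. Libraries of different groups were not compared in this way, and these values do not exclude libraries made from the same RNA.

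Before LPS, livers at 30 °C had lower transcripts for 9 of 18 tested genes of the major urinary proteins, pheromone carriers secreted by the liver, and for 4 of 22 cholesterol synthesis genes. The Mup genes were not among the fixed lists and were not tested as a family. The largest differences were in Mup19 (-6.10 ± 0.93, limma adjusted p = 0.00022), Mup7 (-5.72 ± 1.07), Mup18 (-4.46 ± 0.86), Mup1 (-4.30 ± 0.76) and Mup17 (-3.96 ± 0.49). These genes share reads with near-identical copies, and Mup1 at 30 °C lay near the level of 3 reads. The 4 cholesterol synthesis genes (10 adjusted over the list alone) were Msmo1 (-1.53 ± 0.25, adjusted p = 0.00052), Cyp51 (-1.23 ± 0.26), Sqle (-1.47 ± 0.31) and Idi1 (-1.48 ± 0.32). The list had a median of -0.72 and passed camera (adjusted p = 7.06e-16). That call was lost in the stricter test (adjusted p = 0.0636 with an estimated correlation). Higher at 30 °C were Rad51b (1.97 ± 0.45), a DNA repair gene, Serpina7 (1.80 ± 0.37), which encodes thyroxine-binding globulin, and Gadd45g (1.78 ± 0.32). Soat2 (1.56 ± 0.32), which esterifies cholesterol, and Nap1l1 (1.25 ± 0.27) were also higher. With limma, 44 of 8702 genes differed, 8 higher and 36 lower at 30 °C (n = 5 against 4).

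Oat, an ornithine aminotransferase of pericentral hepatocytes, was also lower at 30 °C at 0 h (-1.53 ± 0.27, limma adjusted p = 0.0017). It was the 1 changed member of 9 pericentral markers (3 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). It was also the 1 changed member of 33 genes of the urea cycle and amino acid catabolism (2 adjusted over the list alone; adjusted p = 0.608 with an estimated correlation). Bile acid synthesis and transport genes leaned lower with 0 of 19 members changed (adjusted p = 0.608 with an estimated correlation). So did unfolded protein response genes with 0 of 22 changed (2 lower adjusted over the list alone; adjusted p = 0.369 with an estimated correlation). None of the 15 genes followed throughout passed at 0 h. Cirbp, a cold-inducible RNA-binding protein gene, differed by -0.59 ± 0.38 (adjusted p = 0.66), and Igfbp1 came closest (1.06 ± 0.41, adjusted p = 0.35).

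A fit of the 0 h libraries alone called 13 genes, and voom weights, added after the data were seen, called 24. Of the genes named at 0 h, Msmo1 and Mup17 kept their call in both. The fit alone ended the calls of Mup19, Mup18, Mup7, Gadd45g, Oat, Soat2, Cyp51, Sqle, Idi1, Serpina7 and Rad51b, and voom weights those of Mup1, Mup7, Gadd45g, Soat2, Sqle, Serpina7 and Nap1l1. No filter and the replicate block also ended the call of Rad51b. The highest limma adjusted p over the other settings was 0.41 for Gadd45g and 0.21 for Mup19 and Mup18. Leaving out single libraries ended some calls at 0 h. For Rad51b these were replicates 2 and 4 at 22 °C and 1, 2 and 4 at 30 °C (limma adjusted p up to 0.18). For Serpina7 it was replicate 3 (0.08) and for Nap1l1 replicate 1 (0.057), both at 22 °C. For Cyp51 they were replicates 3 and 4 at 22 °C (up to 0.056). For Sqle they were replicates 2 and 3 at 22 °C and 2 at 30 °C (up to 0.065), and for Idi1 replicates 3 and 4 at 22 °C and 2 at 30 °C (up to 0.078).

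**Figure D1:**
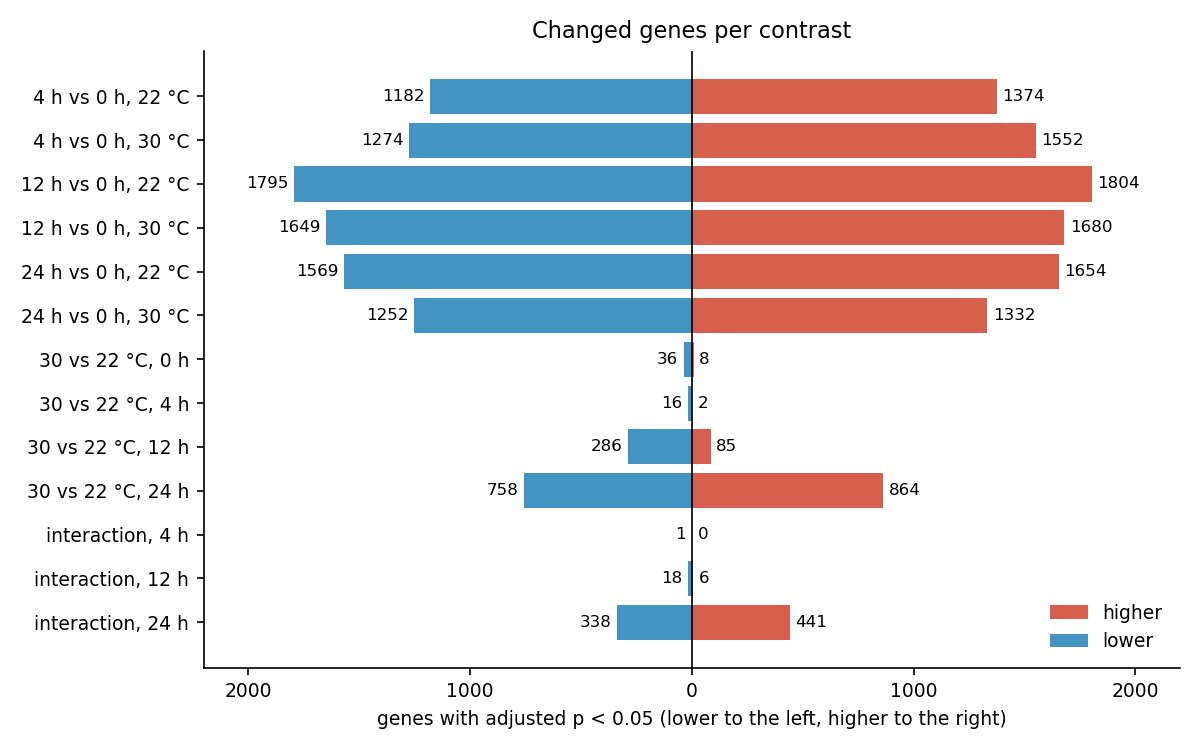
Numbers of genes with limma adjusted p under 0.05 in each contrast among 8702 tested, with higher values to the right and lower values to the left of 0. The temperature contrast holds 44 genes at 0 h and 1622 at 24 h, and the contrasts against 0 h hold between 2556 and 3599.

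At 4 h after LPS, genes of inflammation and of the interferon response rose strongly at both temperatures. Cxcl9, a chemokine induced by interferon gamma, went from 52.7 ± 11.4 to 2598 ± 333 at 22 °C (SD, n = 4 and 4). At 30 °C it went from 45.2 ± 7.13 to 2585 ± 461 (n = 5 and 4). Of 27 acute phase genes, 26 rose at 22 °C and 26 at 30 °C (27 and 26 adjusted over the list alone). Among them were Saa1 (5.38 ± 0.21 and 4.91 ± 0.20), Serpina3n (4.00 ± 0.16 and 4.33 ± 0.15), Lcn2 (5.13 ± 0.23 and 5.04 ± 0.22) and Hp (2.40 ± 0.16 and 2.58 ± 0.15). All 17 members of the list of interferon gamma response GTPases and chemokines rose at both temperatures (17 and 17 adjusted over the list alone). Gbp2 rose by 5.23 ± 0.28 and 5.67 ± 0.27, and Gbp6 by 4.68 ± 0.22 and 4.82 ± 0.21. Of 28 type I interferon response genes, 27 rose at 22 °C and 26 at 30 °C (27 and 27 adjusted over the list alone), Ifi47 by 4.83 ± 0.23 and 4.95 ± 0.22. In limma 1374 genes rose and 1182 fell at 22 °C, and 1552 rose and 1274 fell at 30 °C.

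The largest rises at 4 h at 22 °C were Cxcl10 (6.87 ± 0.39), Ccl4 (6.53 ± 0.58), Mx1 (6.49 ± 0.70), Ccl2 (6.44 ± 0.49) and Socs1 (6.38 ± 0.45). At 30 °C they were Tgtp1 (7.50 ± 0.53), Cxcl10 (6.94 ± 0.36), Calhm6 (6.57 ± 0.55), Mx1 (6.27 ± 0.66) and Cxcl2 (6.09 ± 0.57). Of 18 cytokine and chemokine genes, 16 and 15 rose (17 and 15 adjusted over the list alone). Of 22 NF-kB feedback genes, 21 and 20 rose (22 and 20 adjusted over the list alone), Tnfaip3 by 5.03 ± 0.42 and 5.32 ± 0.40 and Socs3 by 4.76 ± 0.32 and 4.55 ± 0.31. Of 16 antigen presentation genes, 12 rose at either temperature (12 and 12 adjusted over the list alone). Of 15 growth arrest and apoptosis genes, 13 and 12 rose (13 and 13 adjusted over the list alone), Gadd45g at 22 °C by 4.22 ± 0.34. The metal-binding Mt2 rose by 4.87 ± 0.24 and 5.39 ± 0.23. Its list of 11 had 5 rises and 2 falls at either temperature (5 and 2, then 6 and 3, adjusted over the list alone). Of 11 neutrophil and monocyte markers, 7 and 8 rose and at 30 °C 1 fell (7, and 8 with 1 fall, adjusted over the list alone), S100a8 by 3.60 ± 0.35 and 3.37 ± 0.33. These 9 lists passed camera with the preset and with the estimated correlation at both temperatures. At 0 h Ccl2, Tnfaip3 and Socs3 at both temperatures, Ccl4, Mx1 and S100a8 at 22 °C, and Tgtp1 and Cxcl2 at 30 °C lay near or under the level of 3 reads.

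Genes of other functions fell by 4 h. The largest falls at 22 °C were Hdac7 (-4.62 ± 0.72), Ppp1r3c (-4.55 ± 0.60), a glycogen-targeting phosphatase subunit, Gas1 (-4.30 ± 0.59), Fam214a (-4.30 ± 0.49) and Clec14a, which was listed at 0 in the 4 libraries at 4 h. At 30 °C they were Agfg2 (-4.48 ± 0.48), Cavin2 (-4.47 ± 0.48), G0s2 (-4.46 ± 0.40), Ppp1r3c (-4.26 ± 0.57) and Rnf144b (-4.25 ± 0.42). All of these except Fam214a fell to near or under the level of 3 reads. Of 12 endothelial markers, 9 and 7 fell and 1 rose at each temperature (9 and 8 falls and 1 rise each adjusted over the list alone; adjusted p = 0.126 and 0.0896 with an estimated correlation). Kdr fell by -3.70 ± 0.52 and -3.67 ± 0.49, to under 3 reads, while Lyve1 rose at 22 °C by 2.62 ± 0.36. Of 19 bile acid synthesis and transport genes, 9 fell and 1 rose at either temperature (9 and 1 each adjusted over the list alone; adjusted p = 0.324 and 0.374 with an estimated correlation). Of 50 P450 and xenobiotic genes, 7 and 10 fell (4 and 10 adjusted over the list alone; adjusted p = 0.72 and 0.631 with an estimated correlation).

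A few lists passed camera at 4 h at 1 temperature only. Of 22 cholesterol synthesis genes, 12 fell at 22 °C (13 adjusted over the list alone; adjusted p = 0.324 with an estimated correlation), Insig1 by -1.83 ± 0.30. In the interaction this list passed camera, with a more positive change at 30 °C (adjusted p = 0.000237), although 0 members changed (4 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation). Of 22 unfolded protein response genes, 13 rose at 30 °C (13 adjusted over the list alone; adjusted p = 0.136 with an estimated correlation), Xbp1 by 2.71 ± 0.21. Its interaction passed camera (adjusted p = 0.0454), with 0 members changed (1 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation). Of 9 stellate cell markers, 3 fell at 30 °C (3 adjusted over the list alone; adjusted p = 0.374 with an estimated correlation). The interaction of that list did not pass (camera adjusted p = 0.168).

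Of the genes followed throughout, Hspa1b, an inducible heat shock protein gene, rose at 4 h by 2.57 ± 0.51 at 22 °C and 2.67 ± 0.48 at 30 °C (limma adjusted p = 0.00017 and 4.1e-05). Igfbp1 rose by 4.73 ± 0.43 and 2.65 ± 0.41, a difference that did not pass the interaction test (-2.08 ± 0.60, adjusted p = 0.333). Hspa8 rose by 0.99 ± 0.23 and 1.34 ± 0.22. Cpt1a, the carnitine shuttle enzyme of fatty acid oxidation, rose at 22 °C by 1.34 ± 0.27 and differed by 0.49 ± 0.26 at 30 °C (interaction -0.84 ± 0.37, adjusted p = 0.691). It passed at 30 °C without 0 h replicate 2 (adjusted p = 0.039). Cirbp fell by -1.18 ± 0.40 at 22 °C and -1.32 ± 0.38 at 30 °C. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 39.0 ± 17.7 to 1.65 ± 1.15 at 22 °C (SD, n = 4 and 4) and from 23.7 ± 22.0 to 1.34 ± 1.88 at 30 °C (n = 5 and 4), both under 3 reads. Rbm3, another cold-inducible RNA-binding protein gene, rose by 0.60 ± 0.20 and 0.50 ± 0.19, and Pck1 rose at 22 °C by 0.80 ± 0.29.

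Leaving out single libraries ended some of these calls at 4 h. At 22 °C those of Cirbp and Pck1 ended without 0 h replicate 1 or 4 or 4 h replicate 2 or 3 (limma adjusted p up to 0.11 and 0.14). That of Rbm3 ended without 0 h replicate 2 or 3 or 4 h replicate 1 (up to 0.088). At 30 °C that of Rbm3 ended without 0 h replicate 1, 2 or 3 or 4 h replicate 3 or 4 (up to 0.15). Other settings that ended them were no filter for Cirbp, Pck1 and the 30 °C call of Rbm3, upper-quartile rescaling for Pck1 and the 22 °C call of Rbm3, and voom weights for Cirbp and the 30 °C call of Rbm3, which TPM values, array weights and a fit of its groups alone also ended (adjusted p up to 0.22). In 30 °C 4 h replicate 4, 22.0% of the signal lay in 13 genes that match satellite repeat sequence, against at most 1.18% in any other library. Without it 2702 genes changed at 4 h at 30 °C.

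By 12 h after LPS, most P450 and bile acid genes had fallen at both temperatures, while most acute phase and interferon gamma response genes stayed high. Of 50 P450 and xenobiotic metabolism genes, 42 fell and 3 rose at 22 °C, and 40 fell and 2 rose at 30 °C (43 and 40 falls and 3 and 2 rises adjusted over the list alone). Cyp3a25 fell by -2.85 ± 0.26 and -4.09 ± 0.26. Of 19 bile acid synthesis and transport genes, 14 fell at either temperature and 2 and 3 rose (14 and 14 falls and 2 and 3 rises adjusted over the list alone). Abcb11, the bile salt export pump, fell by -3.17 ± 0.31 and -4.60 ± 0.31. Of 27 acute phase genes, 27 and 24 were higher than at 0 h (27 and 25 adjusted over the list alone). They were led by Saa1 (6.24 ± 0.20 and 6.14 ± 0.20), Saa2 (6.17 ± 0.21 and 6.33 ± 0.21) and Lcn2 (6.09 ± 0.22 and 6.15 ± 0.22). Of 17 interferon gamma response GTPases and chemokines, 16 were higher at either temperature (16 and 17 adjusted over the list alone). Those 4 lists passed with the estimated correlation too. Of 28 type I interferon response genes, 25 and 18 were higher (25, and 19 with 1 lower, adjusted over the list alone), which held with the estimated correlation at 22 °C and not at 30 °C (adjusted p = 0.0521 with an estimated correlation). In limma 1804 genes rose and 1795 fell at 22 °C (n = 5 against 4), and 1680 rose and 1649 fell at 30 °C (n = 4 against 5).

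Other large rises at 12 h were Cd14 (6.09 ± 0.29) and Tgtp1 (6.05 ± 0.53) at 22 °C, and Tgtp1 (6.60 ± 0.53) and Saa3 (6.17 ± 0.30) at 30 °C. The largest falls at 22 °C were Clec4g (-4.98 ± 0.50), Cyp26b1 (-4.87 ± 0.69), Sgk2 (-4.86 ± 0.58), Cyp26a1 (-4.62 ± 0.73) and Cyp7a1, all to under the level of 3 reads. At 30 °C they were Hsd3b3 (-5.50 ± 0.49), Klkb1 (-5.40 ± 0.31), Keg1 (-5.35 ± 0.38), Tcea3 (-5.19 ± 0.39) and Nr0b2, of which Hsd3b3, Keg1 and Tcea3 fell to under 3 reads and Nr0b2 was listed at 0 in the 4 libraries. Of 22 unfolded protein response genes, 15 and 14 rose and at 22 °C 1 fell (16 with 1 fall, and 14, adjusted over the list alone), with the glutathione-degrading Chac1 at 4.38 ± 0.47 at 22 °C. Of 31 proteasome genes, 13 and 14 rose (13 and 14 adjusted over the list alone), Psma5 by 1.30 ± 0.26 at 22 °C and Psma1 by 1.06 ± 0.19 at 30 °C. Both lists passed with the estimated correlation at both temperatures.

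Fatty acid synthesis genes fell at 12 h in 12 and 16 of 17 cases (12 with 1 rise, and 17, adjusted over the list alone), Fads1 by -2.24 ± 0.20 and -2.77 ± 0.20. The call at 22 °C was lost (adjusted p = 0.0639 with an estimated correlation) and that at 30 °C held. The list of secreted plasma proteins, including negative acute phase proteins lowered in inflammation, had 20 tested genes. Of these, 15 and 19 fell and at 22 °C 1 rose (15 with 1 rise, and 19, adjusted over the list alone). The retinol carrier Rbp4 fell by -1.28 ± 0.16 and -1.83 ± 0.16. For this list too the 22 °C call was lost (adjusted p = 0.12 with an estimated correlation) and the 30 °C call held. Of 74 nuclear genes of the respiratory chain, 42 and 50 fell (42 and 51 adjusted over the list alone; adjusted p = 0.225 and 0.105 with an estimated correlation). Ndufa6 fell at 22 °C by -1.41 ± 0.20 and Ndufa10 at 30 °C by -1.15 ± 0.14. Of 13 Kupffer cell and macrophage markers, 8 fell and 1 rose at either temperature (9 and 8 falls and 1 rise each adjusted over the list alone; adjusted p = 0.0558 and 0.0571 with an estimated correlation). Slc40a1 fell at 22 °C by -3.28 ± 0.41 and Vsig4 at 30 °C by -4.10 ± 0.48, both to under 3 reads. Of 11 neutrophil and monocyte markers, 8 rose at either temperature and at 30 °C 1 fell (8, and 8 with 1 fall, adjusted over the list alone), S100a8 by 4.94 ± 0.33 and 5.47 ± 0.33, and the list passed with the estimated correlation.

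Of the genes followed throughout, Rbm3 was raised at 12 h by 2.12 ± 0.19 at 22 °C and 2.33 ± 0.19 at 30 °C. Cpt1a was raised by 1.49 ± 0.26 and 1.37 ± 0.26 and Igfbp1 by 4.52 ± 0.41 and 3.45 ± 0.41. Albumin (Alb) fell by -0.94 ± 0.15 and -1.44 ± 0.15. Cirbp rose at 22 °C from 15.4 ± 3.93 to 45.2 ± 10.9 (SD, n = 4 and 5, limma adjusted p = 0.0018). At 30 °C it differed by 0.79 ± 0.38 (limma adjusted p = 0.10), a difference that passed without 12 h replicate 1 (0.015). The interaction of Cirbp did not pass at 12 h (limma adjusted p = 0.647). Fgf21, a fasting hormone gene, averaged 11.3 ± 9.93 at 22 °C (SD, n = 5) and 20.4 ± 1.37 at 30 °C (n = 4) and was under the level of 3 reads at 0 h. Cyp7a1 averaged 0.364 ± 0.635 at 22 °C and was listed at 0 in the 4 libraries at 30 °C. The 22 °C fall of Hspa1b (-1.36 ± 0.48, limma adjusted p = 0.024), to values near 3 reads, was lost without 0 h replicate 1 or 12 h replicate 2 (up to 0.093), with a pseudocount of 5, with no filter and with voom weights (up to 0.096).

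At 24 h the acute phase was still high at both temperatures and P450 genes were still low. Of 27 acute phase genes, 24 were higher and 1 lower than at 0 h at 22 °C, and 25 were higher at 30 °C (25 with 1 lower, and 25, adjusted over the list alone). They were led by Saa2 (6.79 ± 0.21 and 7.02 ± 0.20), Saa1 (6.76 ± 0.20 and 6.80 ± 0.19), Lcn2 (6.36 ± 0.22 and 6.06 ± 0.21) and Saa3 (5.96 ± 0.30 and 6.41 ± 0.28). Of 50 P450 and xenobiotic genes, 44 and 36 were lower and 3 and 4 higher (44 and 37 lower and 3 and 4 higher adjusted over the list alone), Gsta3 at 22 °C by -3.81 ± 0.27 and Cyp1a2 at 30 °C by -5.25 ± 0.25. Of 22 unfolded protein response genes, 17 and 15 were higher and at 22 °C 1 lower (17 with 1 lower, and 15, adjusted over the list alone), Manf at 22 °C by 2.20 ± 0.24 and Pdia6 at 30 °C by 1.74 ± 0.15. Of 11 neutrophil and monocyte markers, 7 and 9 were higher and 1 lower at each temperature (7 and 9 higher and 1 lower each adjusted over the list alone), S100a8 by 4.53 ± 0.33 and 4.80 ± 0.31. These 4 lists passed with the estimated correlation at both temperatures. In limma 1654 genes rose and 1569 fell at 22 °C (n = 5 against 4), and 1332 rose and 1252 fell at 30 °C (n = 5 against 5).

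Of 22 cholesterol synthesis genes, 18 were lower at 24 h than at 0 h at 22 °C (18 adjusted over the list alone), Insig1 by -3.08 ± 0.29 and Hmgcs1 by -2.75 ± 0.29. That list passed with the estimated correlation (adjusted p = 0.0485). At 30 °C 9 of the 22 were higher and 2 lower (9 and 3 adjusted over the list alone; adjusted p = 0.496 with an estimated correlation), Sqle by 2.28 ± 0.30 and Msmo1 by 1.86 ± 0.23. Of 17 interferon gamma response GTPases and chemokines, 10 were still higher at 22 °C (11 adjusted over the list alone), which held with the estimated correlation. At 30 °C 1 was higher and 3 lower (1 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.585). Of 75 cytosolic ribosomal protein genes, 17 were higher and 1 lower at 22 °C, and 44 were higher at 30 °C (16 with 1 lower, and 48, adjusted over the list alone; adjusted p = 0.588 and 0.197 with an estimated correlation). Rplp2 rose at 30 °C by 1.27 ± 0.17. Of 19 bile acid synthesis and transport genes, 14 and 11 were lower and 2 higher at each temperature (15 and 12 lower and 2 and 3 higher adjusted over the list alone), Abcb11 by -4.87 ± 0.31 and -2.91 ± 0.29. The 22 °C call held and the 30 °C call was lost (adjusted p = 0.136 with an estimated correlation).

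The other large changes at 24 h at 22 °C were Cidec (5.71 ± 0.40), Ehd3 (-5.65 ± 0.33), Hsd3b3 (-5.20 ± 0.49) and Apol7a (-5.08 ± 0.49). Each lay under the level of 3 reads in its lower group. Clec4g, of liver sinusoidal endothelium, and Notum fell to 0 in the 5 libraries. At 30 °C they were Orm2 (6.48 ± 0.24), Car3 (-9.12 ± 0.34), Inmt (-6.94 ± 0.35), Serpina6 (-5.92 ± 0.34), Ces1d (-5.81 ± 0.27) and Hao2. Inmt and Ces1d fell to under 3 reads, and Hao2 to 0 in the 5 libraries. With upper-quartile rescaling, which shifted the median of all genes by 0.197 at 30 °C, 1839 genes rose and 852 fell there in limma.

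**Figure D2:**
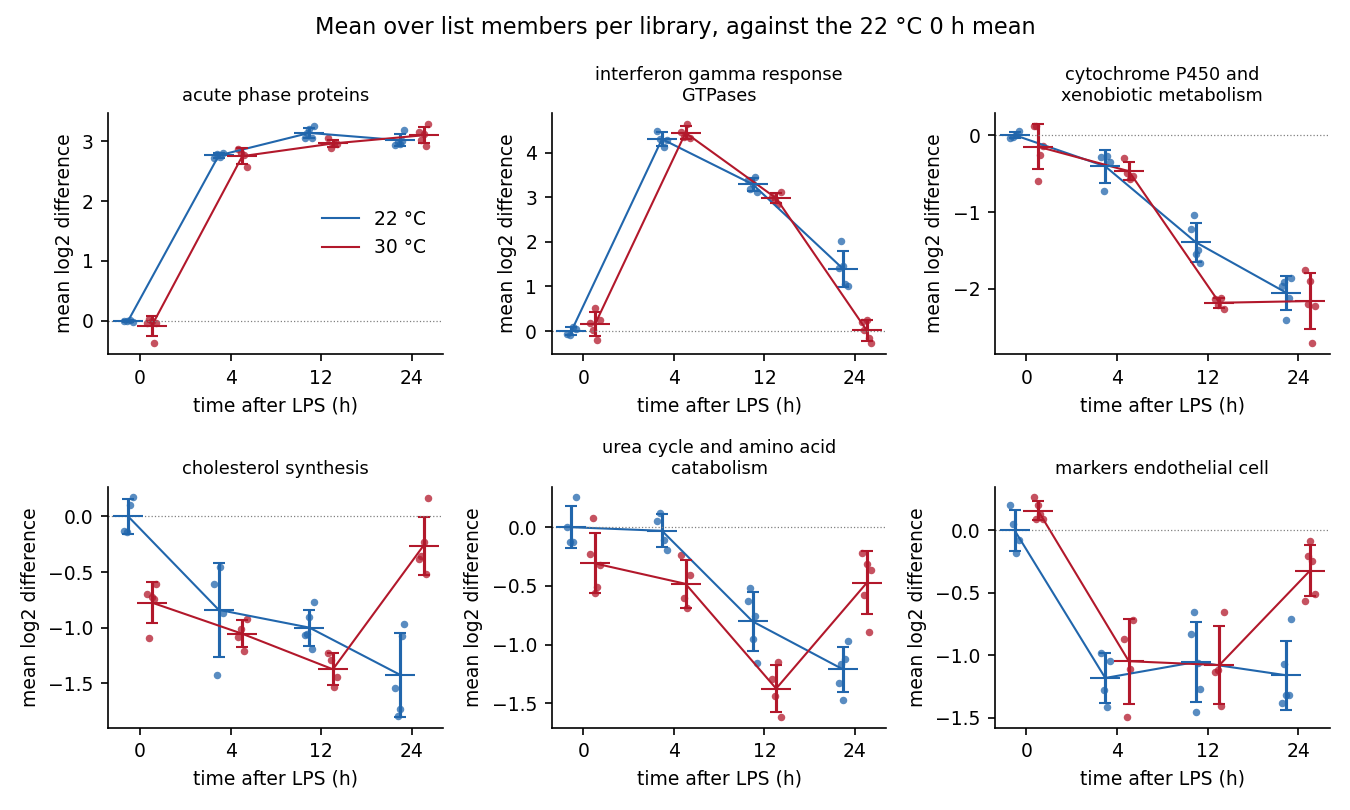
Mean log2(signal + 1) of the members of 6 lists in each library, as a difference from the 22 °C 0 h mean, by time after LPS in evenly spaced categories (points, libraries; bars, mean ± SD; blue, 22 °C; red, 30 °C). Acute phase means rise together at both temperatures, while the GTPase and cholesterol synthesis means differ between temperatures at 24 h, where 12 of 17 and 19 of 22 members passed.

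Between temperatures at 4 h after LPS, few genes differed. Ddit4, an inhibitor of mTORC1 signalling, was lower at 30 °C by -2.27 ± 0.33 (limma adjusted p = 0.00063). Foxo1, a transcription factor of fasting and gluconeogenesis, was lower by -0.99 ± 0.17 (adjusted p = 0.0045), Ubald1 by -1.84 ± 0.31 and Tat, a glucocorticoid-induced aminotransferase, by -1.20 ± 0.23. Mup17 (-2.90 ± 0.51), Mup11 (-1.85 ± 0.41) and Mup16 (-1.76 ± 0.37) were also lower and Xpot (1.32 ± 0.28), a tRNA export factor, higher. Of 19 gluconeogenesis and glycogen genes, 2 were lower, Foxo1 and Tat (6 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation). Of 12 hypoxia response genes, 1 was lower, Ddit4 (2 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation). Another 9 lists passed camera and leaned lower at 30 °C, each with 0 or 1 changed member (0 to 8 lower adjusted over the list alone; adjusted p = 0.1 to 0.653 with an estimated correlation). In limma 2 genes were higher and 16 lower at 30 °C (n = 4 against 4). With no filter on low values 13 were higher and 10 lower, and 8 of the 18 calls were shared. None of the genes followed throughout passed. The smallest adjusted p was that of Pck1 (-1.09 ± 0.29, limma adjusted p = 0.13), which passed without 30 °C replicate 4 (0.027) and with array weights (0.01).

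The count of 18 at 4 h fell to 6, 8 and 9 without replicate 1, 3 or 4 at 22 °C and to 7, 4 and 9 without replicate 2, 3 or 4 at 30 °C. It was 7 in a fit of the 4 h libraries alone and 3 with upper-quartile rescaling, which shifted the median of all genes by 0.143. Both ended the calls of Foxo1, Tat, Mup11, Mup16 and Xpot, and the fit alone also that of Mup17 (limma adjusted p = 0.38). No filter on low values ended those of Mup11, Mup16 and Xpot, array weights those of Mup11 and Mup16, the TPM values that of Mup11 and the replicate block that of Xpot. Over 11 other settings the limma adjusted p ran from 0.0023 to 0.1 for Foxo1, from 0.0027 to 0.28 for Tat, from 0.023 to 0.46 for Mup11, from 0.015 to 0.46 for Mup16 and from 0.0034 to 0.38 for Xpot. Upper-quartile rescaling left the medians of the mitochondrial genome and nuclear receptor lists with the opposite sign. The call of Mup17 was lost without replicate 3 at 30 °C (0.062), and that of Tat without replicate 2 at 22 °C or 2 or 3 at 30 °C (up to 0.099). Those of Mup11 (up to 0.19) and Mup16 (up to 0.14) were lost without replicate 1, 3 or 4 at 22 °C or 2, 3 or 4 at 30 °C. That of Xpot was lost without replicate 1, 3 or 4 at either temperature (up to 0.21).

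At 12 h, livers at 30 °C had lower transcripts for some drug-metabolizing enzymes, some hepatocyte markers and some type I interferon response genes than livers at 22 °C. Of 50 P450 and xenobiotic genes, 20 were lower (31 lower and 3 higher adjusted over the list alone; adjusted p = 0.0918 with an estimated correlation). Cyp2c68 was lower by -1.39 ± 0.20 (limma adjusted p = 3.3e-05) and Cyp2c37 by -1.69 ± 0.27. Of 9 pericentral markers, 6 were lower (7 adjusted over the list alone; adjusted p = 0.0523 with an estimated correlation). Cyp1a2 was lower by -1.36 ± 0.26, glutamine synthetase (Glul) by -1.51 ± 0.31 and Gulo by -1.16 ± 0.25. Of 14 general hepatocyte markers, 7 were lower (8 adjusted over the list alone; adjusted p = 0.0937 with an estimated correlation). Neutrophil and monocyte markers passed camera and leaned the other way, with a median of 0.62 (adjusted p = 0.164 with an estimated correlation). Of the 11 members 0 were higher and 1 lower (1 and 1 adjusted over the list alone), the coagulation factor gene F10. Of 28 type I interferon response genes, 6 were lower (12 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation). Ifit2 was lower by -2.52 ± 0.46, Mx1 by -3.56 ± 0.66 and Ifit3 by -1.79 ± 0.37. In limma 85 genes were higher and 286 lower at 30 °C (n = 4 against 5).

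Of 20 negative acute phase and secreted plasma protein genes, 8 were lower at 30 °C at 12 h (13 adjusted over the list alone, and adjusted p = 0.11 with an estimated correlation). Serpina1a was lower by -0.81 ± 0.14 and Serpina6, the corticosteroid carrier, by -1.74 ± 0.36. Of 33 amino acid catabolism genes, 7 were lower and 1 higher (14 and 3 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation). Bhmt, a betaine-dependent methyltransferase, was lower by -2.54 ± 0.40. Of 19 bile acid genes, 5 were lower (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.164 with an estimated correlation), Abcb11 by -1.46 ± 0.31. Of 17 fatty acid synthesis genes, 2 were lower (5 adjusted over the list alone; adjusted p = 0.166 with an estimated correlation), among them Thrsp (-2.78 ± 0.39). None of the 21 lists that passed camera did so with an estimated correlation. Acute phase genes as a list did not pass (adjusted p = 0.095), with 4 of 27 lower (4 adjusted over the list alone), among them the iron hormone gene Hamp (-1.53 ± 0.31).

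The largest differences at 12 h were Nup133 (2.83 ± 0.83), Olfr1199 (2.50 ± 0.51), Akap17b (1.97 ± 0.55), G0s2 (1.72 ± 0.40) and Zfp638 (1.64 ± 0.36), which were higher at 30 °C. The lower ones were Mup15 (-6.31 ± 1.37), Mup7 (-6.14 ± 1.07), Mup12 (-5.62 ± 1.02), Mup18 (-5.15 ± 0.86) and Mup9 (-4.75 ± 0.90). Nup133 at 22 °C and Mup15, Mup12 and Mup9 at 30 °C lay under 3 reads in many libraries. Olfr1199 is an olfactory receptor gene, and the source of its reads in liver is uncertain and was not tested. Of the genes followed throughout, Cxcl9 was lower at 30 °C (1198 ± 124, SD, n = 4, against 1969 ± 150, n = 5; -0.72 ± 0.16, limma adjusted p = 0.0064). Cirbp was lower by -1.30 ± 0.38 (limma adjusted p = 0.043), a call lost without replicate 1, 2, 3 or 4 at 22 °C or 1 or 2 at 30 °C (up to 0.23), and with a pseudocount of 0.5, no filter, upper-quartile rescaling or a fit of the 12 h libraries alone. The call of Nup133 was lost without replicate 1, 2, 3 or 4 at 22 °C or 1, 2 or 3 at 30 °C (up to 0.13). That of Akap17b was lost without replicate 1 or 4 at 22 °C or 2 or 4 at 30 °C (up to 0.19). No filter also ended both of these calls, a pseudocount of 0.5 and the replicate block that of Nup133, the fit of the 12 h libraries alone that of Akap17b, and voom weights those of Akap17b, Mup15 and Mup9. The count of 371 became 238, 187 and 590 without replicate 1, 2 or 5 at 22 °C and 231, 217 and 241 without replicate 1, 2 or 4 at 30 °C. With array weights, which give noisier libraries less influence, it was 798. With upper-quartile rescaling 103 genes were higher and 182 lower.

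At 24 h after LPS the temperatures differed widely: most interferon gamma response GTPases and chemokines were lower, and most genes of cholesterol synthesis and of complement and coagulation were higher, at 30 °C. Of 17 interferon gamma response GTPases and chemokines, 12 were lower (13 lower and 1 higher adjusted over the list alone). Gbp2 stood at 26.4 ± 8.15 at 30 °C and 353 ± 133 at 22 °C (SD, n = 5 each; -3.67 ± 0.25, limma adjusted p = 3.4e-12). Gbp7 differed by -1.87 ± 0.17 and Cxcl9 by -1.45 ± 0.15 (379 ± 78.6 against 1035 ± 186). Of 22 cholesterol synthesis genes, 19 were higher (19 adjusted over the list alone). Msmo1 was higher by 1.88 ± 0.23 (390 ± 82.9 against 110 ± 41.3) and Hmgcs1 by 1.91 ± 0.28. Of 29 complement and coagulation genes, 19 were higher and 1 lower (22 and 1 adjusted over the list alone), Klkb1 by 2.55 ± 0.29 and C8a by 1.69 ± 0.24. Of 31 proteasome genes, 9 were lower (10 adjusted over the list alone), Psmd7 by -1.12 ± 0.21 and Psmd3 by -0.90 ± 0.17. Of 22 lists that passed camera, these 4 also passed with the estimated correlation (adjusted p = 0.00513, 0.0371, 0.0371 and 0.0371). In limma 864 genes were higher and 758 lower (n = 5 against 5).

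Several lists of energy and nitrogen metabolism leaned higher at 30 °C at 24 h, though none passed with an estimated correlation. Of 33 urea cycle and amino acid catabolism genes, 18 were higher and 2 lower (19 and 2 adjusted over the list alone; adjusted p = 0.129 with an estimated correlation). Cps1, the first enzyme of the urea cycle, was higher by 2.18 ± 0.23, Hgd by 1.81 ± 0.24, Hal by 1.65 ± 0.22 and Kmo by 1.13 ± 0.14. Of 29 fatty acid oxidation genes, 16 were higher and 1 lower (19 and 2 adjusted over the list alone; adjusted p = 0.122 with an estimated correlation). The fatty acid carrier Fabp1 was higher by 2.31 ± 0.27, Hadha by 1.15 ± 0.19 and Acadm by 1.03 ± 0.17. Of 74 nuclear genes of the respiratory chain, 29 were higher (34 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation), Atp5c1 by 0.86 ± 0.14 and Ndufa6 by 1.05 ± 0.19. Of 20 TCA cycle genes, 7 were higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.138 with an estimated correlation), Ogdh by 0.97 ± 0.19.

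Cytosolic ribosomal protein genes were higher at 30 °C at 24 h in 19 of 75 cases (30 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation), Rps26 by 0.76 ± 0.16 and Rpl14 by 0.72 ± 0.15. Of 11 periportal markers, 7 were higher (7 adjusted over the list alone; adjusted p = 0.0601 with an estimated correlation), the gluconeogenic Pck1 by 1.15 ± 0.26. Of 9 pericentral markers, 3 were lower and 1 higher (3 and 1 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation), Cyp1a2 by -2.73 ± 0.25 and Glul by -1.78 ± 0.29. P450 and xenobiotic genes went both ways, with 12 of 50 higher and 13 lower (14 and 14 adjusted over the list alone; camera adjusted p = 0.48). Gstp1 was higher by 2.19 ± 0.21 and Ces1d lower by -2.98 ± 0.27, to under 3 reads. Of 19 bile acid genes, 9 were higher and 4 lower (10 and 4 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation), Slco1b2 by 2.75 ± 0.33 and Cyp27a1 by -1.10 ± 0.20. Acute phase genes also went both ways, with 7 of 27 higher and 6 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.306), Orm2 by 1.86 ± 0.24 and Cd14 by -1.88 ± 0.28.

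The type I interferon, antigen presentation, unfolded protein response, growth arrest and circadian clock lists leaned lower at 30 °C at 24 h, though none passed with an estimated correlation. Of 28 type I interferon response genes, 10 were lower (12 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). Usp18 was lower by -1.86 ± 0.28, to under 3 reads, and Zbp1 by -1.96 ± 0.31. Of 16 antigen presentation genes, 5 were lower (6 adjusted over the list alone; adjusted p = 0.226 with an estimated correlation), the immunoproteasome subunit Psmb10 by -1.93 ± 0.23. Of 22 unfolded protein response genes, 8 were lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation), Hspa5 by -1.04 ± 0.22 and Atf4 by -1.06 ± 0.20. Of 15 growth arrest and apoptosis genes, 5 were lower (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.226 with an estimated correlation), Cdkn1a by -1.61 ± 0.30. Of 15 circadian clock genes, 5 were lower (5 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation), Nr1d2 by -1.40 ± 0.24 and Bhlhe40 by -1.26 ± 0.24.

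Some genes known to respond to cell temperature also differed at 24 h, and others, such as Hspa8 (limma adjusted p = 0.112), did not pass. Cirbp stood at 8.49 ± 4.05 at 30 °C and 50.9 ± 21.8 at 22 °C (SD, n = 5 each; -2.44 ± 0.36, limma adjusted p = 6.7e-06). The other cold-inducible gene, Rbm3, stood at 238 ± 38.3 and 409 ± 49.8 (-0.78 ± 0.18, adjusted p = 0.0021). Hspa1b ran from 7.67 to 44.9 in the 5 libraries at 30 °C (mean 25.2) and from 0 to 8.58 in those at 22 °C (mean 3.47, near the level of 3 reads), a log2 difference of 2.74 ± 0.46 (limma adjusted p = 4.5e-05). Of 19 heat shock and chaperone genes, 4 were higher (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.226 with an estimated correlation). They were Hspa1b, Hsph1 (2.01 ± 0.31), Fkbp4 (1.90 ± 0.36) and Hspe1 (0.85 ± 0.19). Among all tested genes 18.6% passed, so that 4 of 19 is near the share of all genes. Saa1 (0.35 ± 0.19, adjusted p = 0.22), Hp (-0.01 ± 0.14), Lcn2 (-0.41 ± 0.21), Alb (0.10 ± 0.14), Cpt1a (0.05 ± 0.24) and Fgf21 (-1.02 ± 0.58) did not pass.

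Endothelial, stellate and Kupffer cell markers leaned higher at 30 °C at 24 h, with 11 of 34 passing. Of 12 endothelial markers, 5 were higher (6 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation), among them Kdr (2.76 ± 0.47) and Clec4g, which was listed at 0 in the 5 libraries at 22 °C. Of 9 stellate cell markers, 3 were higher (3 adjusted over the list alone; adjusted p = 0.231 with an estimated correlation), Lrat by 2.84 ± 0.45. Of 13 Kupffer cell and macrophage markers, 3 were higher (5 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), Slc40a1 by 1.42 ± 0.39, a call that ended in the fit of the 24 h libraries alone (limma adjusted p = 0.06). That list did not pass camera under any of the 3 other scalings. Among macrophage genes, Cd163 passed with a limma adjusted p = 0.042 and C1qc with 0.02. The call of Cd163 ended without replicate 1, 2 or 4 at 22 °C or 1, 2 or 5 at 30 °C (up to 0.14). That of C1qc ended without replicate 2 or 3 at 22 °C or 3 at 30 °C (up to 0.066). No filter ended both. A pseudocount of 5, the TPM values, voom weights and a fit of the 24 h libraries alone also ended that of Cd163. Of 6 erythroid and platelet markers, 1 was higher and 2 lower (1 and 4 adjusted over the list alone), with a median of -0.713, and the list did not pass camera (adjusted p = 0.183). The largest differences overall were Cacna1d (4.03 ± 0.80), Ehd3 (3.80 ± 0.31), Enho (3.71 ± 0.47), Ppp1r3c (3.71 ± 0.54) and Tnfaip8l1 (3.48 ± 0.55), which were higher. Of these and the markers, Kdr, Lrat, Slc40a1, Ehd3, Enho, Ppp1r3c and Tnfaip8l1 lay near or under 3 reads at 22 °C, where the depth was also lower. Mup12 (-5.54 ± 0.96), Mup7 (-5.06 ± 1.01), Car3 (-4.25 ± 0.34), Mup18 (-4.21 ± 0.81) and Mup17 (-4.13 ± 0.46) were lower. With upper-quartile rescaling, which shifted the median of all genes by 0.159, 1195 genes were higher and 432 lower in limma.

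**Figure D3:**
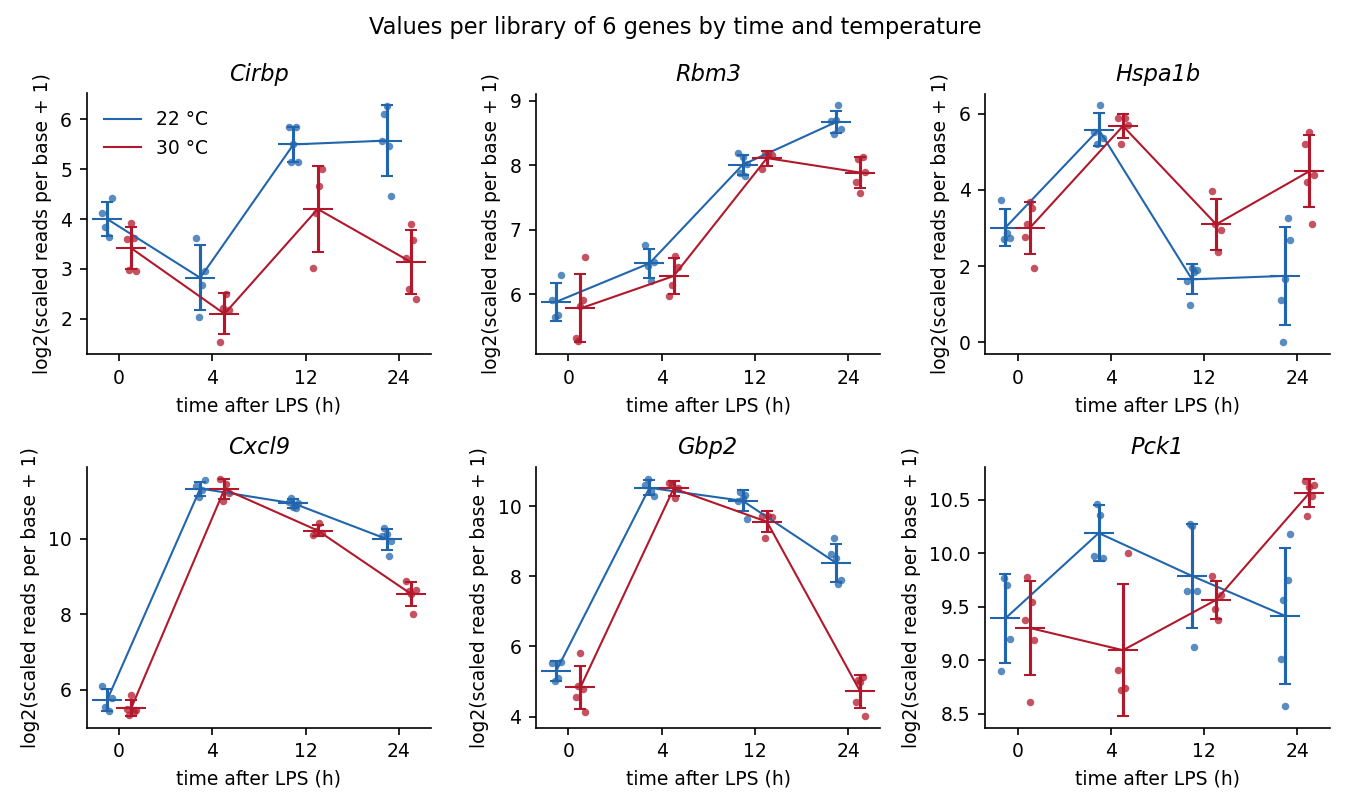
Log2(signal + 1) of 6 genes in each library by time after LPS in evenly spaced categories (points, libraries; bars, mean ± SD; blue, 22 °C; red, 30 °C; lines join the means). At 24 h Cirbp, Rbm3, Cxcl9 and Gbp2 lie lower and Hspa1b and Pck1 higher at 30 °C, with limma adjusted p = 6.7e-06, 0.0021, 2.8e-08, 3.4e-12, 4.5e-05 and 0.0018.

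The interaction tests whether the change since 0 h differed between temperatures. At 24 h, 19 of 22 cholesterol synthesis genes had a more positive change at 30 °C (20 adjusted over the list alone). Msmo1 differed by 3.41 ± 0.34 (limma adjusted p = 1e-07), Idi1 by 3.31 ± 0.45 and Cyp51 by 2.61 ± 0.35, genes that had also been lower at 30 °C at 0 h. Of 17 interferon gamma response genes, 12 had a more negative change (12 adjusted over the list alone), Gbp2 by -3.20 ± 0.36. Both lists passed with the estimated correlation (adjusted p = 0.004 each), unlike the other 16 that passed camera. Among those, 17 of 33 amino acid catabolism genes had a more positive change (18, with 1 more negative, adjusted over the list alone; adjusted p = 0.0906 with an estimated correlation), Cps1 by 2.56 ± 0.33. So had 12 of 29 complement genes (18, with 1 more negative, adjusted over the list alone; adjusted p = 0.0635 with an estimated correlation), Klkb1 by 2.50 ± 0.43. Cirbp had a more negative change at 30 °C (-1.85 ± 0.52, adjusted p = 0.021, and 0.05 with no filter, which ended the call) and Hspa1b a more positive one (2.76 ± 0.67, adjusted p = 0.0071). Rbm3, the other cold-inducible gene, did not pass the interaction test. In limma 441 genes had a more positive and 338 a more negative change at 30 °C. With upper-quartile rescaling, which shifted the median of all genes by 0.179, these were 638 and 207.

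At 4 h 1 gene passed the interaction test, Foxo1 (-1.35 ± 0.24, limma adjusted p = 0.026), and 582 genes had an unadjusted p under 0.05. Its call was lost without 0 h replicate 1 or 4 h replicate 1 or 3 at 22 °C, and without 0 h replicate 2 or 5 or any 1 of the 4 h replicates at 30 °C (adjusted p up to 0.1). It was also lost with upper-quartile rescaling, the TPM values, a fit of these groups alone and voom weights (limma adjusted p 0.012 to 0.18 over 11 other settings). At 12 h 24 genes passed, 6 with a more positive and 18 with a more negative change at 30 °C. Among them were Hacl1 (1.67 ± 0.29), of peroxisomal fatty acid oxidation, and Tcea3 (-3.23 ± 0.55), a transcription elongation factor gene whose 12 h values at 30 °C lay under 3 reads and whose call ended with voom weights (limma adjusted p = 0.076). That count was 3 with no filter (2 more positive and 1 more negative), 53 with a mean of at least 20, 75 with array weights, 76 with the replicate block and 14 with voom weights. It was 7 without 0 h replicate 3 at 30 °C, 3 and 121 without 12 h replicate 2 or 5 at 22 °C, and 3, 8 and 8 without 12 h replicate 1, 2 or 4 at 30 °C. At 4 and 12 h no list that passed camera did so with an estimated correlation.

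Among the genes discussed, Cirbp (ENSMUSG00000045193) lies on chromosome 10 from 80165985 to 80172786 on the plus strand of GRCm38. Rbm3 (ENSMUSG00000031167) lies on chromosome X from 8138975 to 8145880 and Hspa1b (ENSMUSG00000090877) on chromosome 17 from 34956436 to 34959238, both on the minus strand. Cxcl9 (ENSMUSG00000029417) lies on chromosome 5 from 92321347 to 92328079 on the minus strand. All 4 are annotated as protein-coding.

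**Figure D4:**
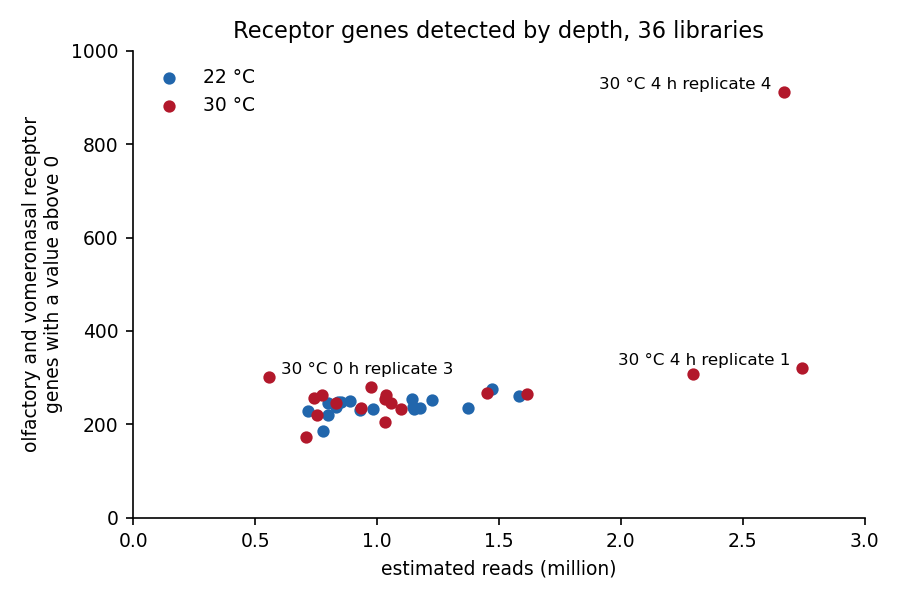
Number of olfactory and vomeronasal receptor genes with a value above 0 in each library against its estimated reads (blue, 22 °C; red, 30 °C). Replicate 4 of the 30 °C 4 h group lists 911 of the 1945 such genes, and the deeper replicate 1 of that group 321.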

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

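The tests of satellite repeat signal, of scaling, of other cell types, of the share of hepatocytes, of depth and of a return to 0 h values were chosen only after the results were seen, while the test of a graded state of each liver and the counts of other splits of the samples were planned.

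Replicate 4 of the 30 °C 4 h group stood apart, with 22.0% of its signal in 13 genes that match mouse satellite repeat sequence against 0.066% to 0.254% in the other 3 libraries of its group. It listed a value above 0 for 911 of 1945 olfactory and vomeronasal receptor genes, against 206 to 321 in the others. Genomic DNA in the library would need such values and may be their source. That count is part of the pattern itself, so it is no separate test of genomic DNA. Greater depth was argued against by replicate 1 of that group, the deeper library, with 321 such genes. The temperature and time of the group were argued against by the highest satellite share of its other libraries (0.254%), below the highest outside it (1.18%). Satellite transcription in that liver was not tested, so that it stays open.

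Cirbp, a cold-inducible gene, was lower and Hspa1b, a heat shock gene, higher at 30 °C at 24 h. Scaling as the whole cause was argued against by the Cirbp difference, which stayed at -2.285 or beyond under 3 other scalings with adjusted p under 0.05. For Cirbp, loss of another cell type was argued against by the marker lists with more tested members. That of erythroid cells and platelets was lowest with a median of -0.713. It mixes cell types and its members went both ways, so that it does not give the loss of either. Loss of lymphocytes (2 of 20 markers tested), cholangiocytes (3 of 9) or adipocyte, pancreas and gut cells (1 of 14) stays open. Hspa1b was not part of this test. A graded state of each liver, such as its temperature, could not be decided: deviations from the group means gave Pearson r = -0.17 (p = 0.31) and Spearman rho = -0.1 (p = 0.56, permutation tests with 100000 resamples, two-sided, 36 libraries), and r = 0.01 without 30 °C 12 h replicate 1 and 22 °C 24 h replicate 5. Body temperature, which was not measured in these data, may differ between the groups and stays untested.

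Many genes differed between temperatures at 24 h. A fuller return towards 0 h values at 30 °C may account for part of this, though the test could not decide. Of 850 such genes with a mean 12 h change of at least 1 log2 unit, 90.5% differed against that change. At 30 °C 337 of 371 risen genes were lower and 432 of 479 fallen genes higher. Among all 2724 genes with such a 12 h change the share was 76.6%. These signs compare the temperatures with each other and not with 0 h. A further change at 22 °C or a passage beyond 0 h values at 30 °C would give the same signs. Lower depth at 22 °C as the whole cause was argued against by the 1244 genes with a mean of at least 100, of which 39.6% passed. A larger share of hepatocytes at 30 °C as the whole cause would raise hepatocyte genes alike. It was argued against by hepatocyte markers above 3 reads in each 24 h library, of which 10 periportal ones differed by a mean of 0.84 ± 0.19 and 7 pericentral ones by -0.70 ± 0.22 (SE over libraries, n = 5 each). The gap was 1.55 (95% interval 1.13 to 1.96), and its interval stayed above 0 under 3 other scalings and without each 24 h library. At 0 h the 9 tested pericentral markers already differed by a mean of -0.708 and the 11 periportal ones by -0.058. Part of the gap may therefore predate LPS, which weakens the argument for the change since 0 h. Markers of endothelial, Kupffer and stellate cells did not decide: 17 above 3 reads were higher by a mean of 0.42 (95% interval 0.06 to 0.78), an interval that included 0 without 22 °C replicate 1, 2, 3 or 4 (lowest limit -0.09) and began at 0, as rounded, without 30 °C replicate 3 or 4. The speed of recovery itself was not tested.

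Single libraries far from the rest of their group were found in 11 of 168 groups, where chance gives about 1 in 20, or 8.4. Groups with the same value in all libraries, such as Cyp7a1 at 30 °C at 12 h, are counted but could not be flagged, so 8.4 is too high. Besides the library above, the satellite share was 0.389% in 30 °C 0 h replicate 3 (others 0.046% to 0.078%). Saa1 was 12400 in 30 °C 4 h replicate 1 (others 8240 to 8620), and Pck1 1030 in 30 °C 4 h replicate 4 (others 421 to 481). Lcn2 was 22.2 in 30 °C 0 h replicate 4 (others 59.5 to 80.8), without which its 24 h interaction passed (limma adjusted p = 0.043). Rbm3 was 244 in 30 °C 12 h replicate 1 (others 284 to 289), and Hspa1b 12.3 in 22 °C 0 h replicate 1 (others 5.51 to 6.36). Fgf21 was 2.97 in 22 °C 4 h replicate 3 and Cyp7a1 0.553 in 22 °C 24 h replicate 4, where the others were listed at 0. These 2 values lie at or under the level of 3 reads (2.974 and 3.216 in those libraries) and stand apart only because the others are 0. The sum of the Mup family was 21100 in 22 °C 4 h replicate 2 (others 74000 to 94000).

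The change since 0 h differed between temperatures in limma for 1 gene at 4 h, 24 at 12 h and 779 at 24 h. At 4 h the gene was Foxo1 (-1.35), whose call ended without 22 °C 0 h replicate 1 or 4 h replicate 1 or 3, or without 30 °C 0 h replicate 2 or 5 or any 4 h replicate (adjusted p up to 0.1), and in 4 other settings (up to 0.18). At 12 h the change was more positive at 30 °C for Tmem147 (2.11), Hacl1 (1.67), Slc25a15 (1.46), Marc1 (1.40) and Ywhag (0.94). It was more negative for Ifit2 (-3.32), Tcea3 (-3.23), Sox9 (-2.71), Thrsp (-2.65), Icam1 (-2.64), Cyp2c37 (-1.88) and Cyp2c68 (-1.34). All of these except Hacl1 and Tcea3 lost their call without 22 °C 12 h replicate 2 or without 30 °C 12 h replicate 1. Others whose removal ended calls were 22 °C 0 h replicate 4 for Tmem147, Slc25a15, Marc1, Ywhag, Sox9 and Cyp2c68, and 30 °C 0 h replicate 3 for these except Cyp2c68 and for Thrsp and Icam1. The same held for 30 °C 12 h replicate 2 for Tmem147, Slc25a15, Marc1, Ywhag, Thrsp, Icam1, Cyp2c37 and Cyp2c68, and for replicate 4 for these except Slc25a15 and Cyp2c37 and for Sox9. For 22 °C 12 h it held for replicate 1 in Tmem147, Slc25a15, Marc1, Ywhag and Icam1, replicate 3 in these except Ywhag, and replicate 4 in Marc1, Ywhag and Icam1. At 0 h it also held for 22 °C replicate 1 in Tmem147, Marc1 and Ywhag, replicate 2 in Marc1 and replicate 3 in Ywhag and Icam1. At 30 °C it held for 0 h replicates 1 and 2 in Marc1, 4 in Ywhag and Icam1 and 5 in Tmem147, Ywhag and Icam1, and for 12 h replicate 3 in Ywhag. Without 1 library the highest adjusted p were 0.11 for Tmem147, 0.08 for Slc25a15, 0.12 for Marc1, 0.09 for Ywhag, 0.06 for Ifit2, 0.062 for Sox9 and Cyp2c68, 0.061 for Thrsp, 0.084 for Icam1 and 0.068 for Cyp2c37. Of these genes, Hacl1 kept its call in every other setting run. No filter ended the calls of the others except Tcea3, voom weights those of Tcea3, Ifit2, Icam1, Marc1, Sox9, Tmem147 and Ywhag, and a fit of the groups alone those of Ifit2, Icam1, Sox9, Thrsp, Tmem147 and Ywhag. TMM ended those of Marc1 and Ywhag, and leaving out 30 °C 4 h replicate 4 that of Ywhag. The limma adjusted p reached 0.19 for Ifit2 and 0.12 for Marc1 in these settings.

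At 24 h the largest more positive changes at 30 °C were those of Tnfaip8l1 (3.98), Zfp507 (3.96), Enho (3.94), A1bg (3.92) and Fam167b (3.69). The largest more negative were those of Car3 (-4.67), Nf1 (-3.55), Thrsp (-3.51), Hbp1 (-3.45) and Tnfrsf23 (-3.44). Among the genes followed throughout, Cirbp (-1.85), Hspa1b (2.76), Pck1 (1.24) and Cxcl9 (-1.25) passed. The call of Pck1 ended without replicate 2 or 3 at 0 h or 1 or 3 at 24 h at 22 °C, or 3 or 5 at 0 h or 1, 3 or 5 at 24 h at 30 °C (limma adjusted p up to 0.085), with no filter and in a fit of its groups alone (up to 0.092). Voom weights ended the calls of Zfp507 and A1bg (limma adjusted p = 0.17 each) and Tnfrsf23 (0.13), and no filter that of Cirbp (0.05). Among cholesterol synthesis genes the values were 3.41 for Msmo1, 3.31 for Idi1, 2.61 for Cyp51 and 2.95 for Hmgcs1. Among interferon response genes they were -3.20 for Gbp2, -2.16 for Gbp6, -1.78 for Gbp7, -2.76 for Xaf1 and -2.28 for Psmb10. Among genes of metabolism and secretion they were 2.56 for Cps1, 2.40 for Hgd, 2.50 for Klkb1, 2.26 for Fabp1, 2.59 for Orm2 and -2.20 for Cd14, and 2.68 for the chaperone gene Hsph1.

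Other splits of the same libraries into groups of the same sizes were counted, the real split included. No other split gave as many genes between temperatures at 0 h (44 genes, 26 in the highest other of 100 splits), 4 h (18 and 6, of 35 splits) and 24 h (1622 and 915, of 100). The same held at 22 °C for 4 h (2556 and 18, of 35), 12 h (3599 and 2766, of 100) and 24 h (3223 and 2671, of 100). It held at 30 °C for 4 h (2826 and 2035), 12 h (3329 and 2466) and 24 h (2584 and 837), of 100 splits each, and for the interaction at 24 h (779 and 9). Between temperatures at 12 h, 2 of 100 splits reached the 371 genes, and the highest other gave 579. For the interaction at 12 h, 3 of 100 splits reached the 24 genes, and the highest other gave 70, several times the real count. Such a count points to a structure of the samples, which was not tested. For the interaction at 4 h, 22 of 100 splits gave at least 1 gene and the highest other 4, so that chance was not excluded.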

How the results depend on the processing

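All alternatives were planned except voom weights and leaving 30 °C 4 h replicate 4 out of every contrast, which were chosen after the data were seen. Of 518 pairs of a gene and a contrast compared, some of genes not reported here, 410 passed in the reported fit and 108 did not, and none reversed. Of the 410 calls, 407 were kept with a pseudocount of 0.5 and 407 with 5, 406 with TMM, 406 with a replicate block, 406 with array weights, 404 without 30 °C 4 h replicate 4, 403 with TPM, 397 with upper-quartile rescaling, 381 with voom weights, 379 with no filter and 374 in fits on the groups of a contrast alone. Of the other 108, 3 passed with upper-quartile rescaling, 2 with array weights and 1 without 30 °C 4 h replicate 4. With a mean of at least 20, 4470 genes were tested and 346 of 346 calls were kept. Of the 235 list calls, 72 held with an estimated correlation. TMM gave 235 (232 shared), the replicate block 235 (227 shared) and fry 256 (205 shared), with none in the opposite direction.

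The temperature contrast at 0 h gave 13 genes in the fit on its groups alone and 24 with voom weights. At 4 h it gave 3 with upper-quartile rescaling and 7 in the fit on its groups alone, and at 12 h 798 with array weights. A mean of at least 20 tested fewer genes and gave 1547 at 4 h and 2304 at 12 h at 22 °C, and 1772 at 4 h at 30 °C. The interaction at 4 h gave 2 with no filter and 0 in limma with upper-quartile rescaling, TPM, fits on its groups alone and voom weights, against 582 genes at an unadjusted p under 0.05 in the reported fit. That at 12 h gave 3 with no filter, 53 with a mean of at least 20, 75 with array weights, 76 with the replicate block and 14 with voom weights. Apart from the number of genes tested, the cause was not tested.

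Leaving out each library gave 4 (without 30 °C replicate 3) to 26 (without 22 °C replicate 2) between temperatures at 4 h. At 12 h it gave 187 (without 22 °C replicate 2) to 590 (without 22 °C replicate 5). The interaction ran from 0 (without 30 °C 0 h replicate 2, for example) to 3 (without 22 °C 0 h replicate 3) at 4 h, and from 3 (without 22 °C 12 h replicate 2) to 121 (without 22 °C 12 h replicate 5) at 12 h. Each of the other counts stayed within 1.5 times its reported value, such as 35 to 52 at 0 h and 1212 to 1783 at 24 h between temperatures and 591 to 976 for the interaction at 24 h. Without 30 °C 4 h replicate 4 the temperature contrast at 4 h gave 9 genes and the interaction 0. Upper-quartile rescaling shared 1296 of the 1622 calls between temperatures at 24 h, with none in the opposite direction, and shifted the median of all genes by 0.110 to 0.197 at 30 °C after LPS and by 0.102 to 0.179 in the interactions. Whether replicate numbers pair the samples could not be decided, and the block was run only as an alternative. Residuals of 118 pairs with the same number had a median correlation of -0.0015 (others -0.002). Yet 12 of 36 libraries correlated best with a library of their own number. The numbers were those of the titles, which in the 30 °C 12 h group differ in part from the submitters' sample numbers. Count models on whole reads were not run because whole reads could not be recovered, nor was a choice among transcripts because values are per gene. Depth limits genes near 3 reads, a signal of 1.33 to 5.05.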

Other observations

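The summed Mup family was chosen only after its values were seen, so its sums are given without a test.

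The major urinary protein genes lie together on chromosome 4 between 59956804 and 62150863 (GRCm38), and their values gene by gene are uncertain because near-identical copies share reads. Their 22 genes were therefore also summed. The folds given here are ratios of geometric means, so they differ from ratios of the printed means. The sum leaves out 4 identifiers without a symbol whose values were identical to those of Mup9, Mup14, Mup15 and Mup16 in every library. Before LPS the sum was 69200 ± 23200 at 22 °C (SD, n = 4) and 11500 ± 3630 at 30 °C (n = 5), 6.00-fold lower. At 4 h it was 68700 ± 32800 and 22000 ± 7430 (n = 4 each), 2.84-fold lower, with overlapping ranges. At 12 h it was 44900 ± 7680 (n = 5) and 4840 ± 1520 (n = 4), 9.47-fold lower, and at 24 h 31100 ± 6190 and 5310 ± 1930 (n = 5 each), 6.12-fold lower. At 0, 12 and 24 h every library at 30 °C lay below every library at 22 °C. The family held 6.63% of all signal at 22 °C and 1.22% at 30 °C at 0 h, and 3.07% and 0.51% at 24 h. With the 4 identical copies added, these shares were 11.3% and 1.89%, and 5.27% and 0.85%, and the sums were 6.68-fold and 6.37-fold lower at 30 °C.

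The share of signal from the mitochondrial genome was 14.3 ± 0.9% at 22 °C and 16.8 ± 1.2% at 30 °C before LPS (SD, n = 4 and 5). At 4 h it was 14.3 ± 1.5% and 12.8 ± 2.5% (n = 4 each), at 12 h 10.2 ± 0.8% and 9.2 ± 0.9% (n = 5 and 4), and at 24 h 8.3 ± 1.0% and 8.7 ± 0.8% (n = 5 each). These shares were not tested.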
